A study of Mus musculus with 2 samples.

How the data were processed

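ChIP-seq for Pol II was made from mouse embryonic fibroblasts grown in DMEM with 10% serum, per the labels' protocols. Whole cell extracts were sonicated to a mean of 500 bp, precipitated, amplified by 18 cycles of ligation-mediated PCR and cut from a gel to select sheared fragments of 50 to 200 nt, per the labels' protocols. Each of the 2 samples has 1 deposited file. The files list read alignments: the signed left-most offset of each read, by chromosome and strand, with reads placed at 1 site and reads placed at 2 sites in separate sections. The authors aligned the reads with Bowtie to mm8 with the options -e 70, -k 2, -m 2, -n 2, -l 36 and --best, per the file headers, and the submitters' processing notes also name Bowtie and mm8. Its version is not given in the sources used here. The deposited files hold no peaks, no scaled signal and no filter on repeated starts. With these options a read that fits more than 2 sites is lost, so repeated sequence is under-represented.

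Each offset was taken as the left-most base counted from 0 and each read as 36 bases long. The first was read from the values, since no description of the format was used here. Reads placed at 1 site on chromosomes 1 to 19, X and Y were used. Reads with the same start and strand were collapsed to 1, and 5′ ends were shifted 60 bp downstream. Opposite strands were offset most often by 85 bp in library 1 and 100 bp in library 2 (lags of 40 to 300 bp in steps of 5 bp). Reads were counted in 500 bp windows. RPM means reads per 1000000 collapsed nuclear reads. Background was the mean of the windows left after 3 rounds of removing called ones, 3.41 reads per window in library 1 and 1.29 in library 2. Windows with a read in either library were tested per library with an exact one-sided Poisson test, Benjamini-Hochberg adjustment and a threshold of 0.01. This made 12 reads the smallest count called in library 1 and 7 in library 2. Called windows with at most 1 window between them were joined to regions, and regions called in both libraries are windows called in both, joined the same way. Overlap meant at least 1 bp.

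Windows called in either library were compared by an exact conditional binomial test. Log2 correlations used a pseudocount of 0.1 RPM. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used. The trimmed-mean scaling (30% of ratios and 5% of levels trimmed on each side) was written for this work. On simulated data with 200 enriched windows for each fold size, the call recovered 30.5% of those at 3-fold, 93% at 5-fold and 100% at 10-fold in library 1, and 11.5%, 48.5% and 96.5% in library 2. The simulated data also held as many windows as were called in the real library, with their real counts, and these counted as true. With them among the calls, at most 0.663% of the simulated calls were false. That figure says nothing on the false share of the real calls. The test between the libraries recovered 2.5% of 2-fold, 14% of 4-fold and 63.5% of 10-fold differences. The flank test recovered 69.5% of 2-fold and 100% of 4-fold inequalities in library 1, and 14.5% and 95.5% in library 2, with at most 1.48% of its calls false. In the simulations of these 2 tests only 200 of 410963 windows and 200 of 12000 summits were unequal at a time. More passed in the real data, so the adjusted threshold was stricter in the simulations and these shares may be too low. At a given fold, library 1 thus recovered more than library 2. For the calls, that fold is over each library's own background, which in RPM was higher in library 1. Each of the 10 regions with the most reads stood further over background in library 2. The simulations therefore do not rank the libraries for a given Pol II site, and their limits hold for Poisson noise only.

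The groups, the tests of the planned comparisons, most alternatives and the rule for named regions were fixed before the data were examined. The rule names the 10 regions called in both with the highest mean RPM over the libraries, the 5 widest, and the 5 windows with the largest ratio each way among those past the threshold, with counts under 3 set to 3 for the ranking only. The analysis of summits and their flanks, the 1 Mb bins, the relation per Mb of chromosome and the comparison of X with autosomes per gene were added after the data were seen. So were the alternatives for summits and flanks, and those that added reads placed at 2 sites, left out windows with many reads per distinct start or left out the chromosome 4 tract. A gene table of GRCm38 was used only for the number of genes per chromosome. Results by promoter, gene body and 19 gene lists had been planned on condition that an annotation of mm8 was at hand. None was used here, coordinates were not converted between builds, and no gene-level result was made, so the lists were not evaluated. Mitochondrial reads entered no comparison, and reads placed at 2 sites entered only the alternative that added them. The alternatives fixed beforehand included all reads kept, no shift or 100 bp, windows of 200 or 1000 bp, a local background over 10 kb, a negative binomial background, a threshold of 0.0001, library 1 thinned to the depth of library 2, other scalings and each library alone.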

Results

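RNA polymerase II (Pol II), the enzyme that transcribes protein-coding genes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse embryonic fibroblasts, connective tissue cells cultured from mouse embryos. Both samples used the monoclonal antibody 8WG16, which binds the repeated C-terminal tail of the largest Pol II subunit. They form 1 group of 2 libraries, called library 1 and library 2 here. The labels give a gel slice of amplified fragments of 150 to 350 bp for library 1 and of 150 to 300 bp for library 2, and a different run code for each, so gel slice, run and sample cannot be separated. Library 1 held 19524971 alignments placed at 1 site and library 2 held 11464418. After repeated starts were collapsed, 17548967 and 10941174 nuclear reads remained. Repeated starts made up 10.1% of the alignments of library 1 and 4.54% of those of library 2. The labels name no separate cultures, so any spread between the libraries may be technical. No input or mock immunoprecipitation was analysed here, and enrichment is against each library's own background. The question that the series title states is where Pol II lies in these cells, and the comparisons are enriched regions against background, 1 library against the other, and chromosome against chromosome.

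Pol II reads were concentrated in many regions, most of them narrow, and the libraries placed a large part of them at the same sites. Library 1 had 54693 enriched regions that covered 81.2 Mb, and library 2 had 90994 regions that covered 218 Mb. Of the library 1 regions, 78.4% overlapped a region of library 2. Of the library 2 regions, 29.8% overlapped one of library 1. Windows of 500 bp called in both libraries numbered 124740, against 13263 expected if the calls were independent over the 4308660 windows tested, a ratio of 9.41. Mappability, which both libraries share, is not in that expectation. Joined into runs, these windows gave 42358 regions called in both libraries, which covered 69.0 Mb. Their median width was 500 bp, 21781 were 1 window wide, 2483 were at least 5 kb wide (4426 when gaps of up to 4 windows were joined) and 176 were at least 20 kb wide. Windows were called by an exact one-sided Poisson test with Benjamini-Hochberg adjustment. The counts rested on that background. A negative binomial background left 23919 and 54811 regions, with 21036 called in both. It was fitted to the windows left after removing called ones, so it allows for only part of the uneven coverage. In library 2 it called 194455 windows, as many as the Poisson test at a threshold of 0.0001. A local background left 14872 and 21710 regions, with 11515 called in both. A threshold of 0.0001 left 22893 called in both.

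The libraries differed in how much of their sequence lay in enriched windows. The share was 19.1% of the reads of library 1 (95% Wilson interval 19.1 to 19.1%) and 53.7% of those of library 2 (53.7 to 53.8%), a ratio of 2.81 (1.76 with the local background). Averaged over the libraries it was 36.4% ± 24.5 (SD, n = 2). Over the windows called in both, the shares were 17.3% and 28.5%, a ratio of 1.64. Background was 0.194 reads per 1000000 (RPM) per window in library 1 and 0.118 in library 2. In windows at least 10 kb from any call it was 0.159 and 0.0784 RPM, against which each fold over background given here would be higher. These intervals, like all Wilson, binomial and Poisson intervals given here, cover counting error only. Across the 410963 windows called in either library, log2 RPM correlated with a Pearson r of 0.57 and a Spearman rho of 0.44, and over the windows called in both with an r of 0.73 and a rho of 0.62. Windows are not independent replicates, so no p-value is attached. Identical read starts were found 262609 times, 1.21 times the mean of 216420 found after displacing one library by 20 to 50 bp. They made up 2.40% of the starts of library 2, and the excess over that mean made up 0.422%. The displaced counts ranged from 208533 to 225611, so the libraries shared more starts than displacement gave. A rule set beforehand counts the libraries as 1 sample where shared starts exceed what coverage predicts. Given the small share, the libraries were still treated as separate samples, which departs from that rule. Each n = 2 given here rests on that choice.

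The region with the most Pol II reads was on chromosome 2 from 117800501 to 117822500 (all coordinates are on mm8). Its level was 1746 ± 922 RPM (SD, n = 2; 1094 in library 1 and 2398 in library 2), 128-fold over background in library 1 and 462-fold in library 2. From 117803001 to 117820000, each 500 bp window held 18.5 to 39.7 RPM in library 1 and 25.5 to 79.2 RPM in library 2, with lower levels toward both ends of the region. Distinct starts occupied 43.6% of its positions and strands in library 1 and 59.6% in library 2, so collapsing repeated starts capped its level. It may also have evened out the windows with the most reads. With all reads kept it stood at 3673 ± 2585 RPM. It held 0.109% of the reads of library 1 and 0.240% of those of library 2. Chromosome 1 from 71513001 to 71588000 followed with 1358 ± 998 RPM over 75 kb (652 in library 1 and 2064 in library 2). A pair of neighbouring regions lay on chromosome 19. The one from 5809001 to 5853500 had 999 ± 367 RPM, and the one from 5792501 to 5806500 had 616 ± 344 RPM (372 in library 1 and 859 in library 2), or 935 ± 584 RPM with all reads kept. The other members of the 10 with the most reads were on chromosomes 2, 10, 15, 6, 13 and 12, with means between 865 RPM and 682 RPM. These 6 had 364 to 580 RPM in library 1 and 913 to 1232 RPM in library 2. Each of the 10 had more RPM in library 2 than in library 1. Together they held 0.559% of the reads of library 1 and 1.32% of those of library 2, and the median region called in both had 1.70 RPM. No gene is named for any region, because no annotation of mm8 was used here.

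**Figure D1:**
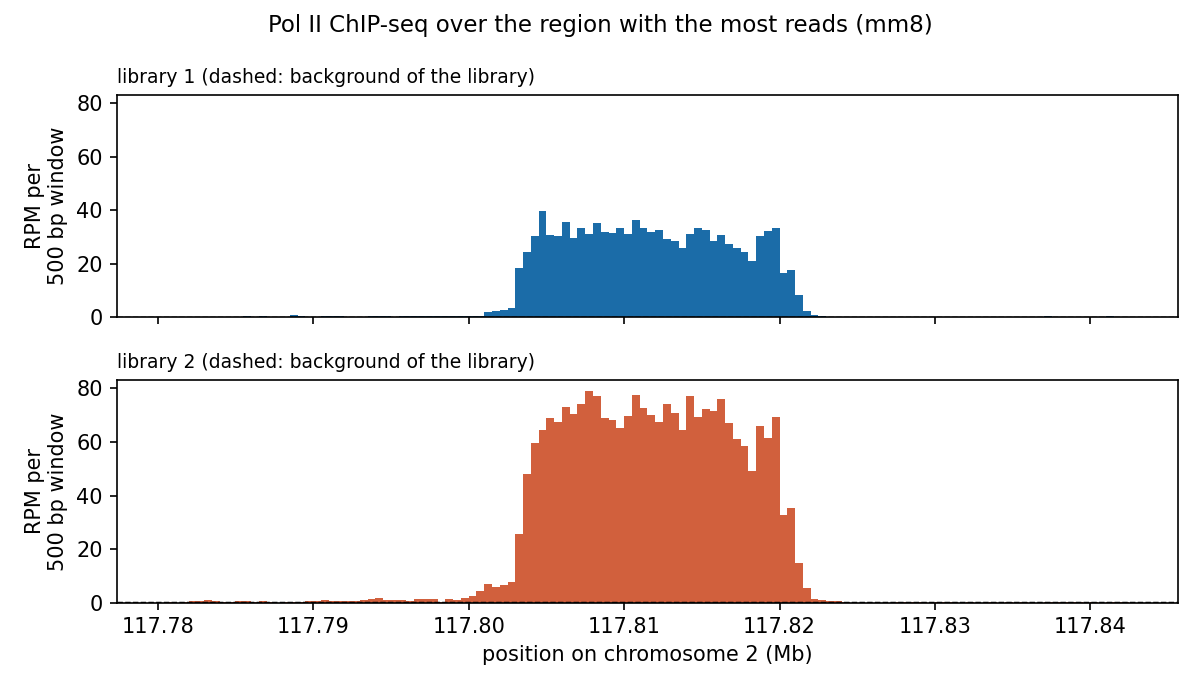
Pol II reads over the region of chromosome 2 with the most reads, in RPM per 500 bp window (vertical axis) against mm8 position in Mb (horizontal axis). The upper panel is library 1, with 49.7 RPM per kb over the region, the lower panel library 2, with 109 RPM per kb, and the dashed line the background of the library.

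Other regions were long stretches of moderate density. The widest region called in both libraries ran over 158 kb of chromosome 2, from 27706501 to 27864500, at 5.48 ± 3.28 RPM per kb (SD, n = 2). The next widest covered 116 kb of chromosome 10 from 119766001 to 119882000 at 7.40 ± 3.39 RPM per kb. Chromosome 12 from 81077501 to 81182000 had 6.52 ± 4.04 RPM per kb over 104.5 kb. Chromosome 6 from 34611001 to 34712000 had 7.59 ± 5.64 RPM per kb over 101 kb. Chromosome 16 from 45676001 to 45765000 had 5.53 ± 3.62 RPM per kb over 89 kb. Across these 5 regions library 1 lay 7.65-fold to 12.9-fold over its background and library 2 lay 33.0-fold to 49.0-fold over its own. By comparison, the 22 kb region on chromosome 2 had 79.3 ± 41.9 RPM per kb.

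Around local peaks of Pol II, reads were often more numerous on one side, and the libraries had more on the same side. Summits were windows called in both libraries with a mean of at least 2 RPM and no higher window within 2 kb, 12008 in all. Reads from 1 to 5 kb to the left and to the right were compared by an exact two-sided binomial test with Benjamini-Hochberg adjustment. These flanks reach beyond the 2 kb in which a summit is highest, so a flank may hold another peak. Such a neighbouring peak was not told apart from Pol II that extends from the summit. Flanks were unequal at 46.8% of the summits in library 1 and at 58.7% in library 2, 52.8% ± 8.45 on average (SD, n = 2). At 12008 windows at least 10 kb from any call, where reads are fewer and the test is weaker, it found 4.09% in library 1 and 0.0666% in library 2. Of the 4853 summits with unequal flanks in both libraries, 4834 leaned to the same side and 19 to opposite sides, 99.6% against the 50% that unrelated sides would give. Unequal mappability of the flanks, which both libraries share, is not in that 50%. Those 4834 were 40.3% of all summits (25.1% with flanks of 1 to 3 kb), and 2462 of them leaned toward higher coordinates. At 4192 summits neither library showed unequal flanks.

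To measure the flanks apart from the choice of side, summits with unequal flanks in 1 library, and their fuller side, were taken from that library and the flank reads counted in the other. These are subsets of the 12008 summits, which were chosen with the reads of both libraries, so summit heights and percentages of the summit are not independent of that choice. Library 1 had more reads on the side given by library 2 at 96.0% of 7052 summits (95% Wilson interval 95.5 to 96.4%). Library 2 had more on the side given by library 1 at 97.5% of 5617 (97.1 to 97.9%). The mean summit window stood 3.39 RPM above background in library 1 and 5.65 RPM in library 2. At 2.5 kb on the fuller side, the level was 23.3% of the summit in library 1 and 35.1% in library 2, and at 2.5 kb on the other side 6.61% and 11.1%. At 10 kb, beyond the flanks used for the choice, it was 13.4% and 19.3% on the fuller side and 6.01% and 9.40% on the other. On the fuller side, 9.74% and 14.2% remained at 19.5 kb.

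At the 4834 summits chosen for unequal flanks to the same side in both libraries, the median ratio of summit to fuller flank was 4.56 in library 1 and 3.20 in library 2, 3.88 ± 0.96 on average (SD, n = 2). At those of the 12008 summits with unequal flanks in the other library, the medians were 5.70 and 3.30. At the 4834, the ratio was 5 or more at 46.7% of summits in library 1 and 29.6% in library 2, and under 2 at 22.4% and 25.8%. Across 4828 of them with a value in both, log2 ratios correlated between the libraries with a Pearson r of 0.77 and a Spearman rho of 0.77. This correlation is across summits, which are not replicates.

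**Figure D2:**
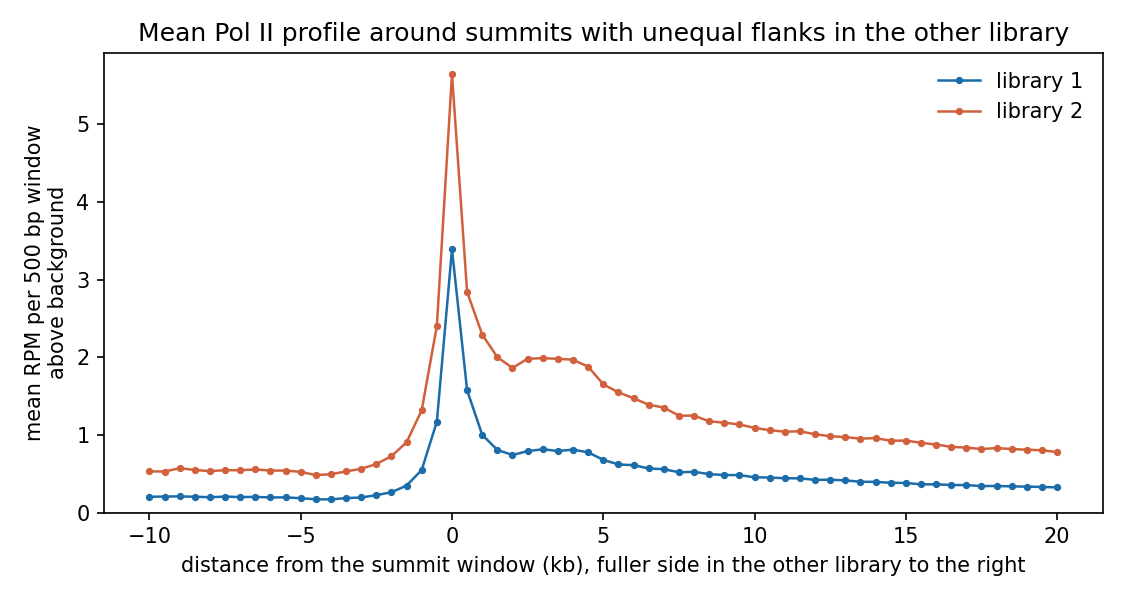
Mean Pol II level above background in RPM per 500 bp window (vertical axis) against distance in kb from the summit window (horizontal axis), with the fuller side on the right. The lines are library 1, over the 7052 of 12008 summits with unequal flanks in library 2, and library 2, over the 5617 with unequal flanks in library 1, each turned by the other's fuller side, drawn without error bars, and at 10 kb on the right they lie at 13.4% and 19.3% of the summit.

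Chromosomes with more genes had more Pol II regions. Over the 19 autosomes, the number of regions called in both libraries correlated with the number of protein-coding genes (Pearson r = 0.91, permutation p = 1e-05, adjusted 1e-05, Spearman rho = 0.90, permutation p = 1e-05, adjusted 1e-05). This p is the smallest that 100000 shuffles can give, the tests are two-sided, and 4 such relations were computed. Without chromosomes 7 and 2, the farthest from the median gene number, r was 0.93. Per Mb of chromosome the relation also held (r = 0.84, permutation p = 2e-05, adjusted 2e-05, rho = 0.83, permutation p = 5e-05, adjusted 5e-05), with r = 0.82 without chromosomes 7 and 11. Gene numbers came from a GRCm38 gene table and need only the chromosome of each gene. Chromosome 11 had the most regions per Mb, 27.4, and chromosome 14 the fewest of the autosomes, 11.9. The autosomal mean was 17.2 ± 3.83 per Mb (SD over 19 autosomes).

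The X chromosome stood below every autosome. It had 637 regions, 3.85 per Mb and 0.66 per protein-coding gene, against 2.08 ± 0.32 per gene on the autosomes, whose lowest value was 1.47. Read density on X was 0.59 of the autosomal mean in library 1 and 0.48 in library 2 (0.53 ± 0.08, SD, n = 2). Outside called windows it was 0.67 and 0.65, so part of the deficit was present in background reads. Reads on the Y chromosome numbered 4833 in library 1 and 2475 in library 2.

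**Figure D3:**
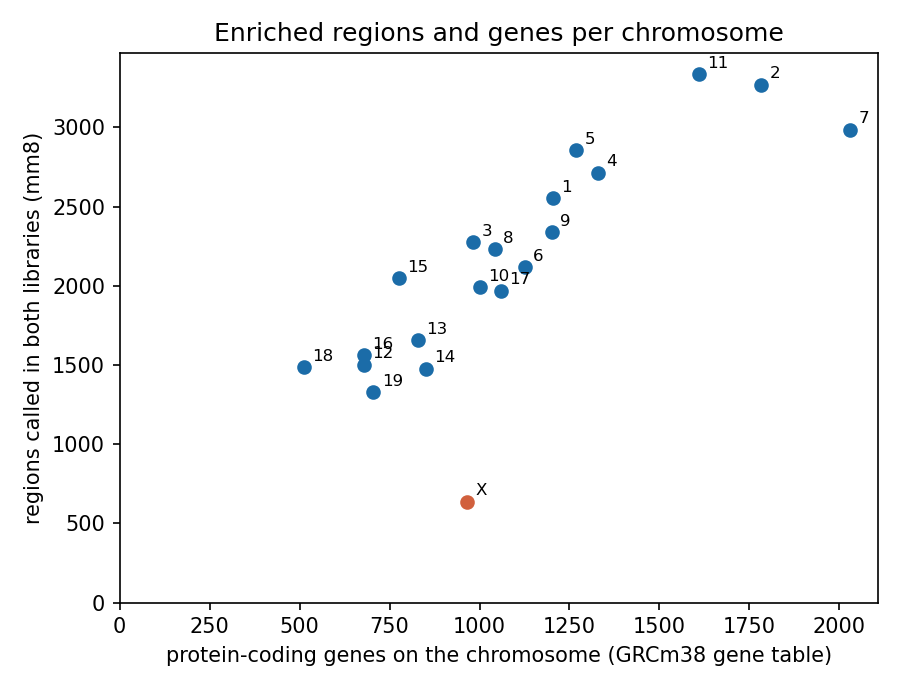
Number of regions called in both libraries (vertical axis, mm8) against the number of protein-coding genes (horizontal axis, GRCm38 gene table), 1 point per chromosome, labelled by chromosome, with the X chromosome in a second colour. The autosomes follow a rising trend (r = 0.91), and X, with 637 regions, lies below it.

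Windows called in both libraries were also unevenly spread along the chromosomes. The bins count windows, not regions, and the windows of a wide region lie side by side. No chance value was computed. Among 2472 bins of 1 Mb with at least 1000 tested windows, 526 held no window called in both libraries, and 11.3% of the bins held 50% of all such windows. The densest bin was chromosome 16 from 24000001 to 25000000, where 36.7% of the tested windows were called in both. Chromosome 19 from 5000001 to 6000000, which holds the neighbouring regions named above, followed with 27.5%. Chromosome 2 from 125000001 to 126000000 had 27.1% and chromosome 10 from 79000001 to 80000000 had 25.3%.

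A small share of windows passed a test for differences between the libraries beyond counting error. On simulated data in which only 200 of 410963 windows differed, it recovered 2.5% of 2-fold and 14% of 4-fold differences. More windows passed in the real data, which makes the adjusted threshold less strict there, so these shares may understate its power. Windows that did not pass may still differ. Scaled to the reads in windows called in both, 4589 of 410963 windows passed an exact two-sided binomial test with Benjamini-Hochberg adjustment, 2260 higher in library 1 and 2329 higher in library 2. Of these, 1467 differed at least 4-fold. Among windows with at least 20 reads over both libraries, 5711 of 198266 passed. With 1 library on each side the test compares these libraries only and covers counting error only. The split rested on the scaling. Scaling by all reads gave 316 windows higher in library 1 and 27254 higher in library 2, and a trimmed-mean scaling gave 7542 and 735. These scalings moved all log2 ratios toward library 2 by 0.72 and -0.37, so ratios within that range have no fixed direction. With all reads kept, 4516 windows were higher in library 1 and 4079 in library 2.

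The 5 windows with the largest ratio toward library 1 all lay in 1 tract, chromosome 4 from 4058501 to 4066000. It held 977 reads in library 1, 19.1-fold over background, and 11 reads in library 2, where background predicts 19.4. The scaled ratio was 90.9 (95% exact interval 50.6 to 183). Within it, the window from 4059501 had 106 reads against 1 (exact interval of the ratio 19.1 to 4326), the window from 4065501 had 87 against 2 (12 to 374) and the window from 4064501 had 75 against 2 (10.3 to 323). The windows from 4065001 and from 4061501 had 79 and 75 reads in library 1 and none in library 2. The exact interval of their ratio began at 21.4 and 20.3. The 5 windows with the largest ratio toward library 2 were on chromosomes 5, 10, 18 and 4. The window on chromosome 5 from 78459501 had 45 reads in library 2 and 2 in library 1, a ratio with a 95% exact interval of 5.74 to 187. On chromosome 10, the window from 34083001 had 77 reads against 6, 12.5-fold higher (interval 5.50 to 35.2), and the window from 34081001 had 40 against 1 (6.62 to 1582). The window on chromosome 18 from 61187001 had 40 against 3 (4.15 to 65.8), and that on chromosome 4 from 64210501 had 37 against 3 (3.82 to 61.1). The largest adjusted p among the 10 was 1.6e-05, by the exact test. All 10 passed it in the same direction under each of the 3 alternatives tried on them, both other scalings and all reads kept.

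**Figure D4:**
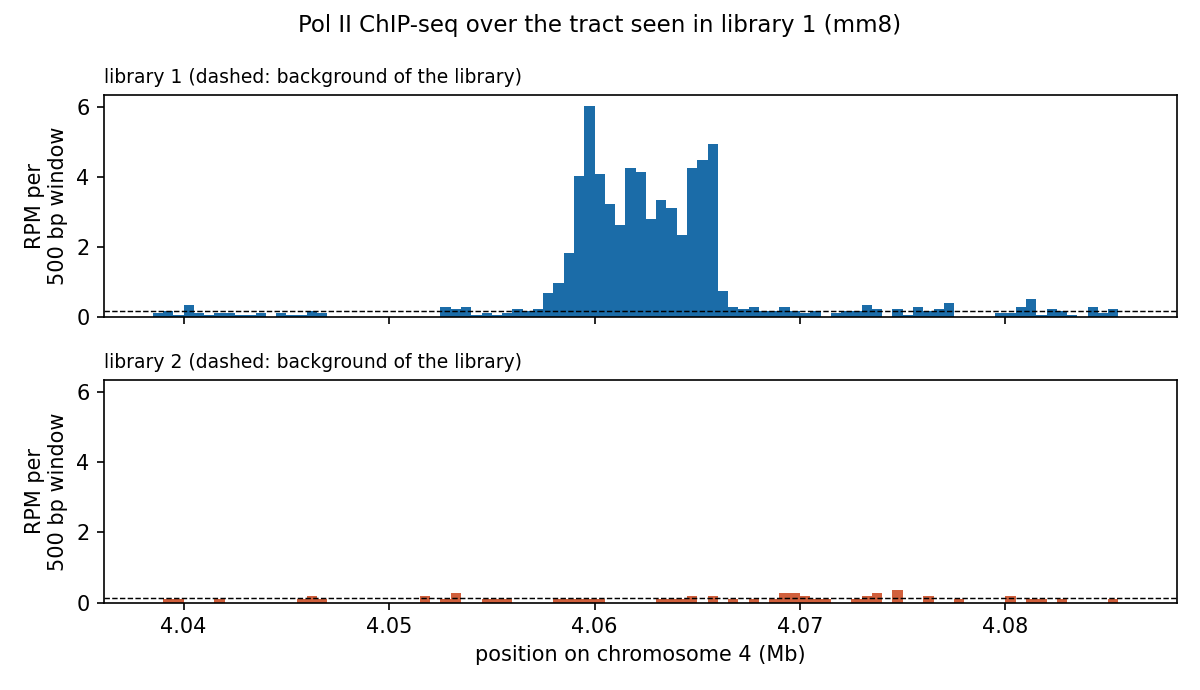
Pol II reads in RPM per 500 bp window (vertical axis) against mm8 position on chromosome 4 in Mb (horizontal axis). The upper panel is library 1, with 977 reads in the tract from 4058501 to 4066000, the lower panel library 2, with 11, and the dashed line the background of the library.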

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

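The tests on the chromosome 4 tract and the mirrored pairing on chromosome 12 were chosen after the result was seen, and the bounds of the others were set before their results, though after the data were first seen.

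Reads placed at 2 sites, which entered only an alternative, formed dense tracts. They are given as alignments with repeated starts collapsed, and a read may be listed at both of its sites. On chromosome 12 from 55631501 to 55661000 there were 5628 such alignments in library 1 and 6687 in library 2, against 24 and 35 reads placed at 1 site. This is 191 and 227 alignments per kb, where the genome-wide mean was 0.381 and 0.199. A test set before its result asked for same-strand starts at 1 fixed distance, with bounds of at least 80% and at most 20% of starts. It gave 40.5% ± 5.21 (SD, n = 2), between the bounds, so it did not decide. The most frequent distance was 506 bp in library 1 and 520 bp in library 2, close to the smallest distance searched, 500 bp. It ran on the tract joined over gaps of up to 9 windows, from 55631501 to 55641500. The longer span was joined over up to 20 windows after that result was seen and gave 42.8%, the mean of 41% at 19289 bp in library 1 and 44.7% at 508 bp in library 2, so the libraries gave no common same-strand distance. On opposite strands, 68.3% of the starts of library 1 and 66.7% of those of library 2 lay in pairs mirrored about position 55646094 in both libraries. That centre was the one with the most pairs, both alignments of a single read can form such a pair, and no chance value was computed. Chromosome 17 from 14698001 to 14759000 held 4497 and 8068 such alignments.

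Mitochondrial reads, also unused, lay on the minus strand for 67.7% of 7609 reads in library 1 (95% Wilson interval 66.6 to 68.7%) and 53.1% of 2961 in library 2 (51.3 to 54.8%). After collapsing repeated starts the shares were 59.2% and 52.7%.

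Library 1 had the lower share of reads in enriched windows, 19.1% against 53.7%, although it was the deeper. Depth argues in the other direction, since thinning library 1 to the depth of library 2 raised the ratio of shares from 2.81 to 3.59. Repeated starts do not account for it, since the ratio was 2.63 with all reads kept. Extra background over one and the same profile predicted equal library ratios at summits and flanks, but at 12593 summits picked with part of the reads and measured with the rest, library 1 had 0.62 of the excess of library 2 at summits and 0.43 in flanks, a quotient of 1.44 (bootstrap interval 1.42 to 1.46, and 1.40 with background taken at least 10 kb from calls). Extra background that is even along the genome is therefore too simple on its own. Background was subtracted as 1 value per library and no input was analysed, so the quotient cannot exclude extra background that is uneven. A mixture of extra background and a profile with less signal beside the summits may hold. So may an effect of gel slice or run, which the design confounds with the libraries. No biological explanation was tested because the libraries form 1 group.

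The tract on chromosome 4 from 4058501 to 4066000 had 977 reads in library 1 and 11 in library 2. Amplified copies of few molecules do not account for it, since 86.6% of its 1128 reads had distinct starts. A tract missing from the DNA of library 2 predicted almost no reads, but library 2 had 0.57 of its background rate (exact Poisson interval 0.28 to 1.02), and its 11 reads in 15 windows stand beside a mean of 0.80 reads per window in the 20 kb on each side. Transcription of the tract in 1 culture and extra copies of it in the DNA of library 1 may each give such a tract and were not tested, and no biological explanation could be tested within 1 group.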

How the results depend on the processing

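Of 77 values of main results under alternatives that kept both libraries, 58 moved by no more than 1.5 times and 19 by more. Of 66 RPM values of named regions, 64 moved by no more than 1.5 times. The others were the chromosome 2 region from 117800501 (3673 RPM) and the chromosome 19 region from 5792501 (935 RPM), both with all reads kept. Part of these tallies was fixed in advance. Other shifts and random thinning can hardly move the RPM of regions this wide, and thinning library 1 leaves the calls of library 2 as they were. The tallies thus overstate stability. Scaling by all reads moved the ratio of each of the 10 named windows by 1.64 times. Leaving out a library gives the value of the other and says nothing on stability with 2 libraries. With the local background, regions were 14872 in library 1, 21710 in library 2 and 11515 in both, and the share of reads in called windows became 6.70% in library 1 and 11.8% in library 2. With the negative binomial background they were 23919, 54811 and 21036. With a threshold of 0.0001 they were 27046, 54811 and 22893. Fewer windows pass these stricter settings by construction. Windows of 200 bp took the share of library 1 to 11.8%. Windows of 1000 bp gave 57770 regions in library 2, and thinning left 35317 in library 1, which depth therefore limits. Each library alone gave 54693 to 90994 regions. Requiring an overlap of 50% of the shorter region moved the shared part of library 1 from 78.4% to 77.9%. For the remaining values that moved, the cause was not tested. A pseudocount of 1 RPM raised the Pearson r between libraries to 0.70. Windows that differed between libraries numbered 27570 scaled by all reads, 8277 with the trimmed-mean scaling and 8595 with all reads kept. The ratio of X to autosomal density was 0.66 outside called windows. Joining windows over gaps of up to 4 gave 4426 regions of at least 5 kb in place of 2483. Flank length, summit level and the choice of summits were varied only after the data were seen. Summits that leaned to the same side in both libraries were 40.3%, or 25.1% with flanks of 1 to 3 kb and 56.4% with flanks of 1 to 10 kb. They were 50.5% for summits of at least 4 RPM. Also added after the data were seen, reads placed at 2 sites brought the regions called in both from 42358 to 44705, and windows that differed numbered 4573 without the chromosome 4 tract. Likewise, leaving out 30 windows with over 5 reads per distinct start, which hold 0.146% and 0.155% of all reads and of which 24 were called in both libraries, gave 42359 regions called in both. The alternatives for promoters, gene bodies and gene lists were not run, for want of an annotation of mm8 here. No paired analysis was possible because the 2 libraries form 1 group.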

Other observations

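The runs of differing windows and the test on X were added after the data were seen, and the bounds of that test were set before its result. The longest run higher in library 1 covered 58 kb of chromosome 11 from 3041501 to 3099500, with 9461 reads against 2779, a scaled ratio of 3.48 toward library 1. Over their own backgrounds the libraries were closer there, 23.9-fold in library 1 and 18.5-fold in library 2. The scaled ratio does not subtract background, which was higher in library 1. This run also held 754 and 239 alignments of reads placed at 2 sites. The longest run higher in library 2 lay inside the strong region of chromosome 1, from 71541501 to 71562000, with 6620 reads in library 2 against 3079, a scaled ratio of 2.10. On chromosome 4 from 63487001 to 63502500, library 2 was 46.5-fold over background and library 1 was 4.45-fold, a scaled ratio of 3.86 toward library 2.

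The X chromosome had 0.66 regions per protein-coding gene (exact Poisson interval 0.61 to 0.71), below each of the 19 autosomes. A hypothesis was that fewer reads on X, as in cells with 1 copy of it, may be enough to explain this. Autosomal reads were thinned to the X density outside called windows, keeping 0.67 of the reads in library 1 and 0.65 in library 2, with the smallest counts called left as they were. The thinned autosomes gave 1.06 ± 0.16 regions per gene (SD over autosomes), and the lowest, chromosome 6, gave 0.82. Thinning to this level thus lowered the autosomal value but left every autosome above X. Stronger thinning, as 1 copy of X could call for, was not run, so fewer reads at that level stay possible. Windows with a read placed at 1 site in either library covered 104 of 166 Mb on X, against 133 of 160 Mb on chromosome 3, of similar length. The regions per Mb and per gene were not corrected for this. The effect of sequence on X in which reads have no unique place, and of the kinds of genes there, was not tested and stays open.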
